A study of Homo sapiens with 12 samples.

How the data were processed

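RNA sequencing was carried out on 12 libraries of HPB-ALL, a human cell line from T-cell acute lymphoblastic leukaemia (T-ALL). Per the labels, the cells had been infected with lentiviruses for doxycycline-inducible overexpression, selected with a drug and treated with doxycycline or with DMSO, the vehicle. There were 3 lines, for TAL1, for LMO1 and for both (TAL1/LMO1), and 2 replicates per line and treatment. The dose and duration of doxycycline are not given in the sources used here. No line without a transgene was among the 12 libraries.

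The submitters' processing notes name STAR 2.5.2a, featureCounts and DESeq2 1.12.4, and the genome build hg19. The authors deposited a table of raw counts per gene, with 63677 genes and no normalization; whether the counts are of reads or of read pairs is not stated. The authors also deposited a DESeq2 table for each line. Per the file headers, its columns hold a mean normalised count (a signal averaged over libraries), a log2 fold change with its standard error, a score (the Wald statistic), and a p-value with its adjusted p-value. The authors' design formula is not given in the sources used here, and the direction of their ratio was read from the induced transgenes.

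Everything below was computed from the deposited counts unless the authors' table is named. Genes were kept by edgeR's filterByExpr with the 6 groups, which left 16287 genes. Of the others, 29971 had 0 counts in all libraries, among them all 13 mitochondrially encoded mRNAs. Library sizes were scaled by TMM, and levels are given in CPM (counts normalised to the scaled library size), with the SD over the 2 libraries of a group. A quasi-likelihood model in edgeR 4.0.16 (R 4.3.3, robust estimation) had 1 mean per group, which left 6 residual degrees of freedom shared by all comparisons. The model also pooled the spread across genes, with a median of 66.0 prior degrees of freedom, so most p-values rest largely on other genes' spread. Its F tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested in that comparison. Log2 fold changes are those of the model, with a prior count of 0.125, and their SE is the size of the change divided by the square root of F. Where the counting error of the log2 change, from the summed counts of its groups, was larger, it is given as the SE instead. The common biological coefficient of variation was 3.35%. These p-values measure only the spread between these libraries, since nothing in the sources says that replicates were separate cultures.

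For each line, doxycycline was compared with DMSO. The responses were compared between lines by contrasts within the same model, including TAL1/LMO1 against the sum of both single responses on the log2 scale. The DMSO libraries of the lines were also compared. The comparisons, tests, alternatives, gene lists and the rule for named genes were fixed before the data were examined. The rule took TAL1 and LMO1, then the 10 largest rises and 10 largest falls per line among called genes with a mean of at least 2 CPM in either group and no overlap between the libraries of both treatments. Clone names, pseudogenes and antisense transcripts were left out. From each gene list that was called or had at least 2 called members, it took up to 4 members with the smallest p. For differences of responses it took 5 genes per direction, and for the DMSO libraries 3 per direction. Genes named outside the rule are identified where they appear. Gene types came from GENCODE 29, on another genome build than the counts, by Ensembl identifier; 96.6% of the tested genes had one. No coordinates were used.

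The 25 gene lists held 503 genes, and 23 lists had at least 3 tested members. Lists were tested with camera in limma 3.58.1 on voom values, with a preset inter-gene correlation of 0.01, and adjusted over the lists within each comparison. Camera asks whether a list moved more than other genes. It was repeated with an estimated correlation, and with fry, which asks whether the members move, on balance, one way. Counts adjusted over the list alone used the p-values of its members only. Leaving out members with 3 or fewer counts in a group moved the median of no list of at least 14 tested members by more than 0.03 on the log2 scale.

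Library totals lay between 14865073 and 15917713 counts. A count of 3 in a library, the upper limit that a count of 0 allows with 95% confidence, equals at most 0.198 CPM. Where a group had 0 counts, the fold is a lower bound against 3 counts over the group. Where it had 1 to 3 counts, the ratio is given with its 95% exact interval (Clopper-Pearson). These limits cover counting error only.

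The procedure was tested on simulated data. Simulated fold changes of 2 were recovered in 86.6% of 67 genes for the TAL1 line, 89.6% for the LMO1 line and 92.5% for the TAL1/LMO1 line. Among 15545, 15545 and 15525 unchanged genes, 10, 14 and 19 were called. The simulated folds were 1.5, 2 and 4, in few genes and with the spread of the fitted model. In the data, 60.2% of genes changed in the TAL1/LMO1 line. The median absolute log2 change of called genes was 0.26 in the TAL1 line and 0.29 in the LMO1 line, below the 0.58 of a 1.5-fold change. Recovery and false calls in those settings were not simulated. Alternatives were DESeq2's size factors, total counts, no low-count filter, a stricter filter of 1 CPM in 2 libraries, DESeq2 1.42.0, only the 4 libraries of a line, an absolute log2 fold change of at least 1, a replicate block, and leaving out each library in turn. With 1 library left in a group, that library is assumed to vary like those of the other groups. Figures were drawn with matplotlib 3.10.9. Levels of XIST and Y-linked genes are not given.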

Results

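RNA levels were measured in 3 derivatives of the T-ALL cell line HPB-ALL that carried inducible TAL1, LMO1, or both. TAL1 is a basic helix-loop-helix transcription factor and LMO1 a LIM-domain protein that bridges transcription factors; both are oncogenes of T-ALL. Each of the 6 groups (3 lines with DMSO or doxycycline) had 2 libraries, so n = 2 per group throughout. The TAL1/LMO1 doxycycline libraries had 14865073 and 15104650 counts, and the highest total was 15917713, in replicate 2 of the LMO1 line with DMSO. The first principal component held 52.2% of the variance of log CPM. Along it, the TAL1/LMO1 DMSO libraries lay between the libraries of the single lines and the TAL1/LMO1 doxycycline libraries. This component therefore holds a difference between lines that was present with DMSO as well as the change with doxycycline. The second component, with 27.4%, separated the TAL1 line from the LMO1 line.

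Doxycycline raised the transgene of each line, and the line with both reached the highest levels of each. In the TAL1 line, TAL1 (ENSG00000162367) rose from 3.97 ± 0.13 to 39.2 ± 5.3 CPM (SD), a log2 fold change of 3.30 (SE 0.29, adjusted p = 0.0028). In the LMO1 line, LMO1 (ENSG00000166407) rose from 2.84 ± 1.5 to 226 ± 19 CPM, a log2 fold change of 6.31 (SE 0.43, adjusted p = 0.00060). In the TAL1/LMO1 line, TAL1 rose from 5.21 ± 3.0 to 900 ± 45 CPM (log2 7.43, SE 0.21, adjusted p = 3.1e-08) and LMO1 from 3.67 ± 4.6 to 1539 ± 53 CPM (log2 8.71, SE 0.38, adjusted p = 7.4e-07). With doxycycline, TAL1 was therefore 22.9 times as high in the TAL1/LMO1 line as in the TAL1 line, and LMO1 6.81 times as high as in the LMO1 line. The gene that a line did not carry stayed low: TAL1 averaged 0.131 CPM in the LMO1 line under both treatments, and LMO1 averaged 0.195 and 0.162 CPM in the TAL1 line. The DMSO libraries of the TAL1/LMO1 line differed from each other, with TAL1 at 3.08 and 7.34 CPM and LMO1 at 0.449 and 6.89 CPM. Reads of the construct and of the cell's own gene were not told apart. Without replicate 2 of the TAL1 line with DMSO, the rise of TAL1 in that line was 3.27 with an adjusted p of 0.051. The size of the other rises depended on single DMSO libraries. In the TAL1/LMO1 line, LMO1 rose by 7.79 without DMSO replicate 1 and by 11.70 without DMSO replicate 2, and TAL1 by 6.92 and 8.17. In the LMO1 line, the rise of LMO1 was 128-fold without DMSO replicate 1 and 57.3-fold without DMSO replicate 2.

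**Figure D1:**
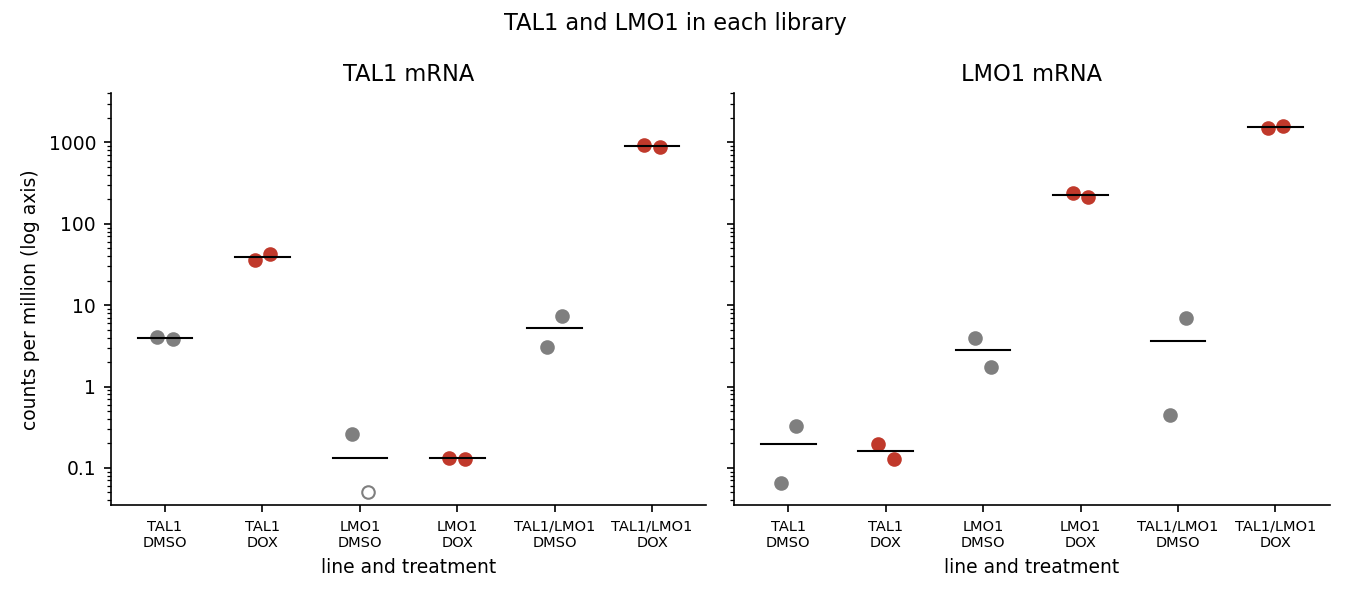
CPM of TAL1 (left) and LMO1 (right) on a log axis in each of the 12 libraries; grey points are DMSO, red points doxycycline, black lines group means, and the open point a library with 0 counts, drawn at the bottom of the axis. With doxycycline, TAL1 averaged 39.2 CPM in the TAL1 line and 900 CPM in the TAL1/LMO1 line.

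The TAL1/LMO1 line addresses what both factors do together, and doxycycline changed 9812 of its 16287 tested genes, or 60.2%. Of these, 4644 rose and 5168 fell, and 2414 changed by at least 1 on the log2 scale. By total counts the split was 5611 and 4277, so which direction held more genes depends on the scaling. RUNX1, which encodes a haematopoietic transcription factor, rose from 208 ± 13 to 1141 ± 10 CPM, and MYC, a proto-oncogene and regulator of growth, fell from 559 ± 26 to 49.8 ± 1.3 CPM. ALDH1A2, a retinoic acid-producing enzyme, rose from 2.12 ± 1.8 to 509 ± 22 CPM, with 0.834 and 3.41 CPM in the DMSO libraries. Its log2 fold change of 7.90 (SE 0.18) became 7.21 without the first of these and 9.23 without the second. DOCK1, an activator of the GTPase RAC, fell from 1251 ± 22 to 9.39 ± 0.07 CPM, a log2 fold change of -7.06 (SE 0.08, adjusted p = 2.6e-76). Among other large rises, SEMA4A had a log2 fold change of 6.81 (SE 0.22) and CRTAM, with 4 counts over the DMSO libraries, of 6.51 (SE 0.72). TFPI was 301 times as high (95% interval 82.9 to 2490), KRT73 86.5 times (23.6 to 720) and SORBS2 94.2 times (16.5 to 3758). PRR9 had 0 counts with DMSO and was at least 96.4-fold higher with doxycycline; GCSAML was at least 28.2-fold and DNAJC5B at least 25.6-fold higher. HEPACAM also had 0 counts with DMSO and averaged 2.41 CPM with doxycycline. Large falls included the kinase gene FGR (log2 -4.93, SE 0.21), NCR2 (-4.76, SE 0.25), PGPEP1L (-5.01, SE 0.24), SERTAD4 (-4.93, SE 0.42) and RIMBP2 (-4.52, SE 0.66). DAAM2 and FAM196A were at least 36.1-fold and 28.8-fold lower. GOLGA8S was at least 21.8-fold lower and TRBV30 70.2 times as low (19.1 to 586), but both belong to families of similar sequences whose reads are hard to tell apart. Over the fits with 1 library left out, SEMA4A lay between 6.38 and 7.38 and CRTAM between 5.94 and 7.42 on the log2 scale. SERTAD4 lay between -6.47 and -4.21, PGPEP1L between -5.70 and -4.57 and NCR2 between -5.34 and -4.37. Genes with few counts in a group moved more: TFPI lay between 7.13 and 11.22 and KRT73 between 5.34 and 9.42. SORBS2 lay between 5.38 and 8.55 and TRBV30 between -9.07 and -5.07.

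Genes described as activated by TAL1 in T-ALL rose together in the TAL1/LMO1 line. Of 15 tested members, 14 rose and none fell, and 14 rose when adjusted over the list alone (camera adjusted p = 1.7e-12; adjusted p = 0.0030 with an estimated correlation). Examples are RUNX1 (2.46, SE 0.05), TRIB2 (2.53, SE 0.05), the cytokine signalling factor STAT5A (5.41, SE 0.25) and CBFA2T3 (1.15, SE 0.05). Among 18 partners of the TAL1 complex, 11 rose and 4 fell, the same as adjusted over the list alone; TAL1 and LMO1 themselves are in this list. Without them, a test added after the data were seen, 9 of 16 rose and 4 fell (camera adjusted p = 0.0065; adjusted p = 0.17 with an estimated correlation). With them the camera adjusted p was 0.00028 and the adjusted p = 0.063 with an estimated correlation, and LYL1 (2.35, SE 0.08) was among its members, and so was MYB, which went from 433 ± 28 to 941 ± 30 CPM. MYB, RUNX1, GATA3, ETS1, TCF12 and CBFA2T3 are in both the partner list and the TAL1-activated list, so these lists are not independent. The list of T-ALL transcription factor oncogenes, which also holds both transgenes, had 5 of 8 members higher and 1 lower, both also when adjusted over the list alone (camera adjusted p = 0.013; adjusted p = 0.068 with an estimated correlation). Without TAL1 and LMO1 that list was not called (camera adjusted p = 0.31). All 4 tested GIMAP genes, GTPases of lymphocytes, rose, 4 when adjusted over the list alone, but the list was not called (camera adjusted p = 0.15).

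Genes of the cortical thymocyte stage fell in the TAL1/LMO1 line. Of these, 14 of 17 were lower and 2 higher, also when adjusted over the list alone (median log2 -1.10, camera adjusted p = 2.8e-06; adjusted p = 0.014 with an estimated correlation). The DNA polymerase gene DNTT fell from 370 ± 5.9 to 30.0 ± 2.0 CPM (log2 -3.63, SE 0.06), and RAG2, part of the receptor recombinase, had a change of -3.32 (SE 0.16). Targets of E proteins, the transcription factors that TAL1 pairs with, were lower in 17 of 20 cases and higher in 2, both also when adjusted over the list alone (median -1.23, camera adjusted p = 3.8e-08; adjusted p = 0.014 with an estimated correlation). PTCRA, RAG1, RAG2, CD4, CD1A, CD1B, CD1E and DNTT are in both this list and the cortical thymocyte list. PTCRA and IL7R are also in the NOTCH list, so these lists are not independent. MYC is in both the NOTCH list and the list of MYC targets and ribosome biogenesis genes. CD1E, an antigen-presenting molecule, had a change of -1.59 (SE 0.05), whereas IGLL1, a surrogate light chain, rose by 2.47 (SE 0.05). Among NOTCH targets, 11 of 15 fell and 3 rose, also when adjusted over the list alone (median -1.34, camera adjusted p = 1.2e-05; adjusted p = 0.053 with an estimated correlation). They included MYC (-3.49, SE 0.05), CR2 (-2.61, SE 0.06), NOTCH3 (-1.79, SE 0.05) and NOTCH1 (-1.30, SE 0.04). T-cell receptor genes moved both ways. Of these, 13 of 27 rose and 11 fell, also when adjusted over the list alone, and the list was not called (camera adjusted p = 0.27). In it the adaptor gene LCP2 (2.72, SE 0.06), the receptor constant region TRAC (1.73, SE 0.05) and CD28 (1.37, SE 0.05) rose and CD247 fell (-1.20, SE 0.05).

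Growth and proliferation genes fell in the TAL1/LMO1 line. Of 27 MYC targets and ribosome biogenesis genes, 26 fell and none rose, 26 when adjusted over the list alone (median -1.33, camera adjusted p = 1.6e-19; adjusted p = 0.0030 with an estimated correlation). Examples were ODC1 (-1.83, SE 0.05), SRM (-1.97, SE 0.06) and NCL (-1.39, SE 0.05). All 25 mitosis genes fell, 25 when adjusted over the list alone (median -0.64, camera adjusted p = 1.7e-12; adjusted p = 0.0052 with an estimated correlation). BUB1B had a change of -1.22 (SE 0.05) and PLK1, a mitotic kinase, of -0.85 (SE 0.05). DNA replication genes fell in 25 of 27 cases, 25 when adjusted over the list alone with 1 higher (camera adjusted p = 2.5e-11; adjusted p = 0.045 with an estimated correlation). RRM2, which makes nucleotides, changed by -1.29 (SE 0.05) and MCM2 by -0.94 (SE 0.05). Glycolysis genes were lower in 15 of 24 cases and higher in 5, with 15 and 6 when adjusted over the list alone (camera adjusted p = 0.021; adjusted p = 0.57 with an estimated correlation). The glycolytic enzyme ENO1 fell (-1.65, SE 0.05) and PKM rose (0.91, SE 0.05). Cholesterol synthesis genes were lower in 16 of 22 cases and higher in 2, with 17 and 2 when adjusted over the list alone (camera adjusted p = 0.0064; adjusted p = 0.053 with an estimated correlation). HMGCS1 fell (-0.83, SE 0.06) and INSIG1, a brake on this pathway, rose (0.90, SE 0.05).

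Immediate early and activation genes were higher in 12 of 19 cases and lower in 3 in the TAL1/LMO1 line, also when adjusted over the list alone (camera adjusted p = 0.0043; adjusted p = 0.11 with an estimated correlation). NR4A3 was at 3.84 (SE 0.17), EGR1 at 3.24 (SE 0.14) and DUSP2 at -1.55 (SE 0.08). Targets of the tumour suppressor p53 were higher in 10 of 21 cases and lower in 3, also when adjusted over the list alone (camera adjusted p = 0.031; adjusted p = 0.088 with an estimated correlation). TP53INP1 (2.36, SE 0.06) and the death gene PMAIP1 (1.30, SE 0.05) rose and AEN (-1.88, SE 0.08) fell. Interferon response genes were higher in 12 of 22 cases and lower in 6, with 13 and 6 when adjusted over the list alone (camera adjusted p = 0.023; adjusted p = 0.11 with an estimated correlation). RSAD2 was at 2.26 (SE 0.18) and USP18 at -1.84 (SE 0.16). Amino acid stress genes under ATF4 split into 8 higher and 11 lower of 23, also when adjusted over the list alone, and the list was not called (camera adjusted p = 0.50). Of the 95 named genes called in this line, 92 kept the call whichever single library of the line was left out. The adjusted p rose to 0.31 for GIMAP2, 0.13 for GIMAP7 and 0.27 for BLNK without doxycycline replicate 1; GIMAP2 also lost the call without DMSO replicate 1, and the others without either DMSO library.

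**Figure D2:**
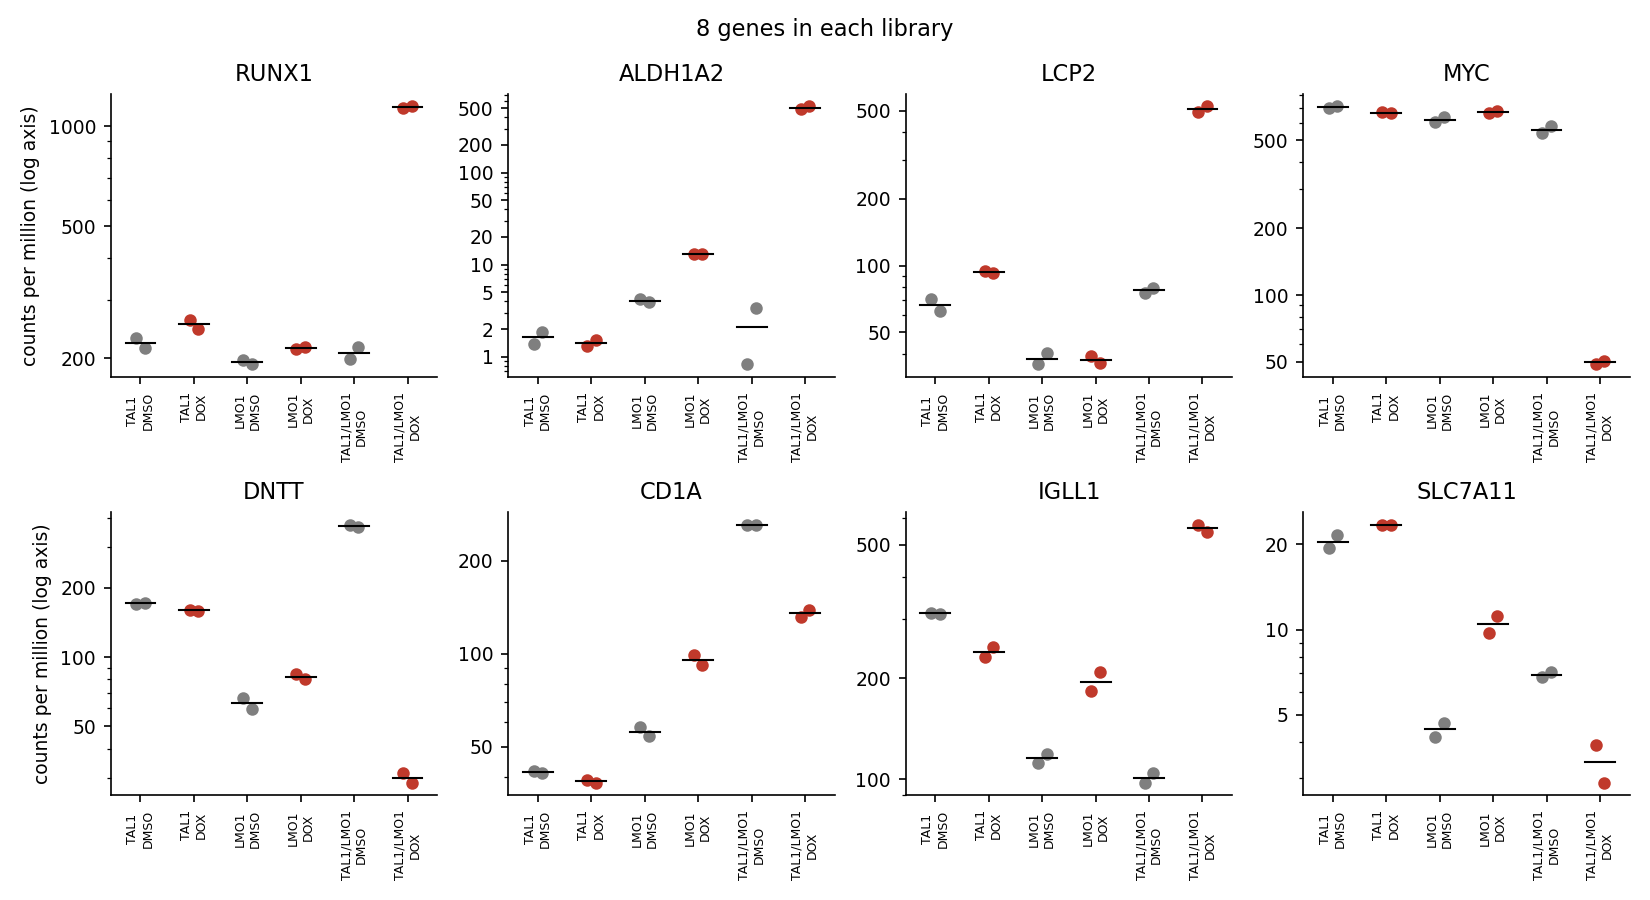
CPM of 8 named genes on log axes, with a separate range per gene, in each of the 12 libraries; grey points are DMSO, red points doxycycline and black lines group means. In the TAL1/LMO1 line RUNX1 rose from 208 to 1141 CPM and MYC fell from 559 to 49.8 CPM. IGLL1 fell in the TAL1 line and rose in the LMO1 line and the TAL1/LMO1 line.

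The TAL1 line asks what TAL1 does alone, and doxycycline changed 299 genes in it, 160 higher and 139 lower. By total counts the split was 216 and 57, with DESeq2's size factors in edgeR 146 and 158, and by DESeq2 itself 71 and 130. Only 29 changed by at least 1 on the log2 scale, 29 higher and 0 lower. IL21R, a cytokine receptor, rose from 6.55 ± 0.84 to 19.5 ± 0.3 CPM (log2 1.57, SE 0.13, adjusted p = 1.0e-14). PI16, with 2 counts over the DMSO libraries, was 120 times as high (95% interval 32.9 to 998). With 1 library left out, its log2 fold change lay between 5.81 and 9.93. GPR18 (2.32, SE 0.33), GIMAP6 (2.60, SE 0.42), RAP1GAP2 (1.22, SE 0.14) and the cytokine gene IL16 (1.11, SE 0.15) rose. ID1, an inhibitor of E proteins, fell from 22.9 ± 0.02 to 14.9 ± 0.07 CPM (log2 -0.62, SE 0.10, adjusted p = 2.3e-05), and MRPL12 fell (-0.48, SE 0.09). IGLL1 fell from 312 ± 0.3 to 240 ± 12 CPM (-0.38, SE 0.05). CFTR, a chloride channel, had a change of 1.32 (SE 0.16, adjusted p = 4.4e-05), but 19.5 and 12.7 CPM with doxycycline stood against 790 CPM in the LMO1 line with DMSO. Other genes high in the LMO1 line were also raised in doxycycline replicate 1, by a median of 1.56% of their level in that line. Whether this was RNA in the sample or reads assigned to the wrong library cannot be told from counts. Taking such a share out, a step chosen after the data were seen, left CFTR at 0.67 (SE 0.18, adjusted p = 0.060); without doxycycline replicate 1 it was 0.98 (adjusted p = 1.0e-06). The subtraction left the number of called genes at 295, of which 286 had been called before.

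GIMAP genes rose in the TAL1 line, 3 of 4 over all genes and 4 when adjusted over the list alone (camera adjusted p = 4.4e-11; adjusted p = 0.027 with an estimated correlation). GIMAP7 went from 9.28 ± 0.31 to 18.6 ± 1.4 CPM. MYC targets and ribosome biogenesis genes were lower in 6 of 27 cases, and in 18 when adjusted over the list alone (median -0.15, camera adjusted p = 1.4e-19; adjusted p = 0.0062 with an estimated correlation). NCL, a nucleolar protein, was at -0.22 (SE 0.04), with an adjusted p of 0.16 without doxycycline replicate 2. Mitosis genes were lower in 1 of 25 cases and in 2 when adjusted over the list alone (median -0.08, camera adjusted p = 1.9e-07; adjusted p = 0.027 with an estimated correlation). These 3 lists were called with either correlation, and the other 11 only with the preset one. TAL1-activated genes had 3 of 15 members higher, 4 when adjusted over the list alone (camera adjusted p = 0.0025; adjusted p = 0.069 with an estimated correlation). ARID5B (0.47, SE 0.10) had an adjusted p of 0.17 without DMSO replicate 2. RUNX1 (0.18, SE 0.05) had 0.47 without that library and 0.36 without doxycycline replicate 1. E-protein targets had 2 of 20 lower and 1 higher, with 6 and 2 when adjusted over the list alone (camera adjusted p = 0.00074; adjusted p = 0.12 with an estimated correlation, and 0.093 with the preset one without doxycycline replicate 2). Glycolysis genes had 4 of 24 lower and 1 higher, with 7 and 1 when adjusted over the list alone (camera adjusted p = 1.1e-05; adjusted p = 0.29 with an estimated correlation).

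Among the remaining called lists of the TAL1 line, the adjusted p was 0.00074 for the ATF4 list (lower), 7.7e-08 for DNA replication (lower) and 0.0025 for natural killer genes (higher). Of the 5 natural killer genes only NKG7 passed the test, and 3 had 3 or fewer counts in a group; without these 3 the median went from 1.37 to 0.71. For these lists the adjusted p was 0.12, 0.097 and 0.070 with an estimated correlation. NKG7, a granule protein of cytotoxic cells, had a log2 fold change of 0.79 (SE 0.11). NOTCH targets (lower) had 0.018, and 0.12 without DMSO replicate 1 and 0.064 without doxycycline replicate 1. Partners of the TAL1 complex had 0.020, but 0.33 once TAL1 and LMO1 were left out of the list, and 0.38 without DMSO replicate 2 and 0.10 without doxycycline replicate 1. T-cell receptor signalling (higher), in which LCP2 rose by 0.50 (SE 0.06), had 0.040. Without DMSO replicate 2, doxycycline replicate 1 or doxycycline replicate 2, its adjusted p was 0.21, 0.11 and 0.096. T-ALL oncogenes had 0.040, but 0.998 without TAL1 and LMO1, and no other member passed the test; the list had 0.21 without DMSO replicate 2 and 0.092 without doxycycline replicate 1. The p53 targets (higher), in which TP53INP1 rose by 0.55 (SE 0.09), had 0.040; without DMSO replicate 1, DMSO replicate 2 or doxycycline replicate 1 it was 0.077, 0.075 and 0.17. In the order given, these 5 lists had an adjusted p of 0.22, 0.22, 0.39, 0.17 and 0.12 with an estimated correlation.

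Most changes in this line were small, with a median absolute log2 fold change of 0.26 among called genes. Leaving out 1 library gave 111 called genes without DMSO replicate 1, 100 without DMSO replicate 2, 130 without doxycycline replicate 1 and 155 without doxycycline replicate 2, and of 45 named genes with a call 14 kept it in all 4 fits. These were PI16, GIMAP6, GIMAP7, GPR18, IL21R, CFTR, RAP1GAP2, IL16, ID1, MRPL12, IGLL1, LCP2, NKG7 and TP53INP1.

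The LMO1 line asks the same of LMO1, and doxycycline changed 349 genes, 192 higher and 157 lower, with 20 changed by at least 1 on the log2 scale. By DESeq2 the split was 101 and 117. SERINC5 rose from 6.47 ± 0.21 to 17.8 ± 0.9 CPM (log2 1.46, SE 0.13, adjusted p = 5.2e-14), and CD1A, a surface molecule of cortical thymocytes, from 56.0 ± 2.6 to 95.6 ± 4.9 CPM (log2 0.77, SE 0.06, adjusted p = 2.6e-16). DOCK5 (1.62, SE 0.28), MFAP4 (1.16, SE 0.11), EPSTI1 (1.03, SE 0.19) and BEST1 (1.02, SE 0.17) rose as well. ALDH1A2 rose from 4.05 ± 0.20 to 13.1 ± 0.05 CPM (adjusted p = 0.0022). Its adjusted p was 0.053 without DMSO replicate 2, 0.075 without doxycycline replicate 1 and 0.079 without doxycycline replicate 2. CCBE1 fell from 3.33 ± 0.17 to 0.754 ± 0.24 CPM (log2 -2.13, SE 0.33, adjusted p = 3.9e-06), and RGS6 (-1.53, SE 0.28), LRIG1 (-0.86, SE 0.17), ANXA1 (-0.73, SE 0.12) and the lysosomal protease gene LGMN (-0.72, SE 0.08) fell too. With 1 library left out, DOCK5 lay between 1.24 and 2.13 and CCBE1 between -2.49 and -1.84.

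Cortical thymocyte genes rose in the LMO1 line. Of these, 8 of 17 were higher and none lower, 11 when adjusted over the list alone (median 0.19, camera adjusted p = 7.1e-19; adjusted p = 0.0021 with an estimated correlation). CD1D (0.57, SE 0.08) and CD1C (0.58, SE 0.09) were among them. E-protein targets were higher in 7 of 20 cases, 10 when adjusted over the list alone (median 0.16, camera adjusted p = 2.6e-12; adjusted p = 0.011 with an estimated correlation). IGLL1 rose from 116 ± 5.2 to 196 ± 18 CPM and the receptor gene IL7R by 0.43 (SE 0.06). NOTCH targets were higher in 3 of 15 cases, 6 when adjusted over the list alone (camera adjusted p = 4.2e-08; adjusted p = 0.025 with an estimated correlation). The receptor gene NOTCH3 rose by 0.35 (SE 0.04). The ATF4 and amino acid stress list had 12 of 23 members higher, 14 when adjusted over the list alone (median 0.18, camera adjusted p = 3.9e-17; adjusted p = 0.0095 with an estimated correlation). In it the amino acid transporters SLC7A11 (1.24, SE 0.15), SLC6A9 (0.97, SE 0.11) and SLC7A5 (0.36, SE 0.04) and the factor ATF5 (0.56, SE 0.05) rose. TAL1-activated genes were higher in 2 of 15 cases, ALDH1A2 and CBFA2T3 (0.37, SE 0.05). Adjusted over the list alone, 7 were higher and 1 lower (camera adjusted p = 0.00061; adjusted p = 0.025 with an estimated correlation).

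MYC targets and ribosome biogenesis genes fell in the LMO1 line in 5 of 27 cases, 11 when adjusted over the list alone with 1 higher (median -0.10, camera adjusted p = 6.8e-12; adjusted p = 0.0095 with an estimated correlation). ODC1, an enzyme of polyamine synthesis, was at -0.26 (SE 0.04) and LDHA at -0.40 (SE 0.06). Glycolysis genes were lower in 11 of 24 cases, 12 when adjusted over the list alone (median -0.19, camera adjusted p = 1.1e-17; adjusted p = 0.056 with an estimated correlation). ENO1 was at -0.32 (SE 0.04), PKM at -0.31 (SE 0.05) and TPI1 at -0.26 (SE 0.05). The adjusted p was 1.2e-05 for mitosis (lower), and 0.025 with an estimated correlation. T-ALL oncogenes had 1 of 8 members higher, LMO1 itself, and 3 when adjusted over the list alone. Their adjusted p was 1.2e-05 (0.023 with an estimated correlation), and 0.027 without TAL1 and LMO1 (0.0996 with an estimated correlation). The adjusted p was 7.5e-05 for partners of the TAL1 complex (higher; 0.014 without TAL1 and LMO1, and 0.22 with an estimated correlation as well), 5.0e-06 for T-cell receptor signalling (higher), 1.6e-05 for DNA replication (lower) and 0.0099 for cholesterol synthesis (lower), and in that order the adjusted p was 0.056, 0.068, 0.11 and 0.056 with an estimated correlation. Cholesterol synthesis had 0.14 without DMSO replicate 2 with the preset correlation. Leaving out 1 library gave 284 called genes without DMSO replicate 1, 224 without DMSO replicate 2, 165 without doxycycline replicate 1 and 155 without doxycycline replicate 2. Of 44 named genes with a call, 30 kept it in all 4 fits.

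**Figure D3:**
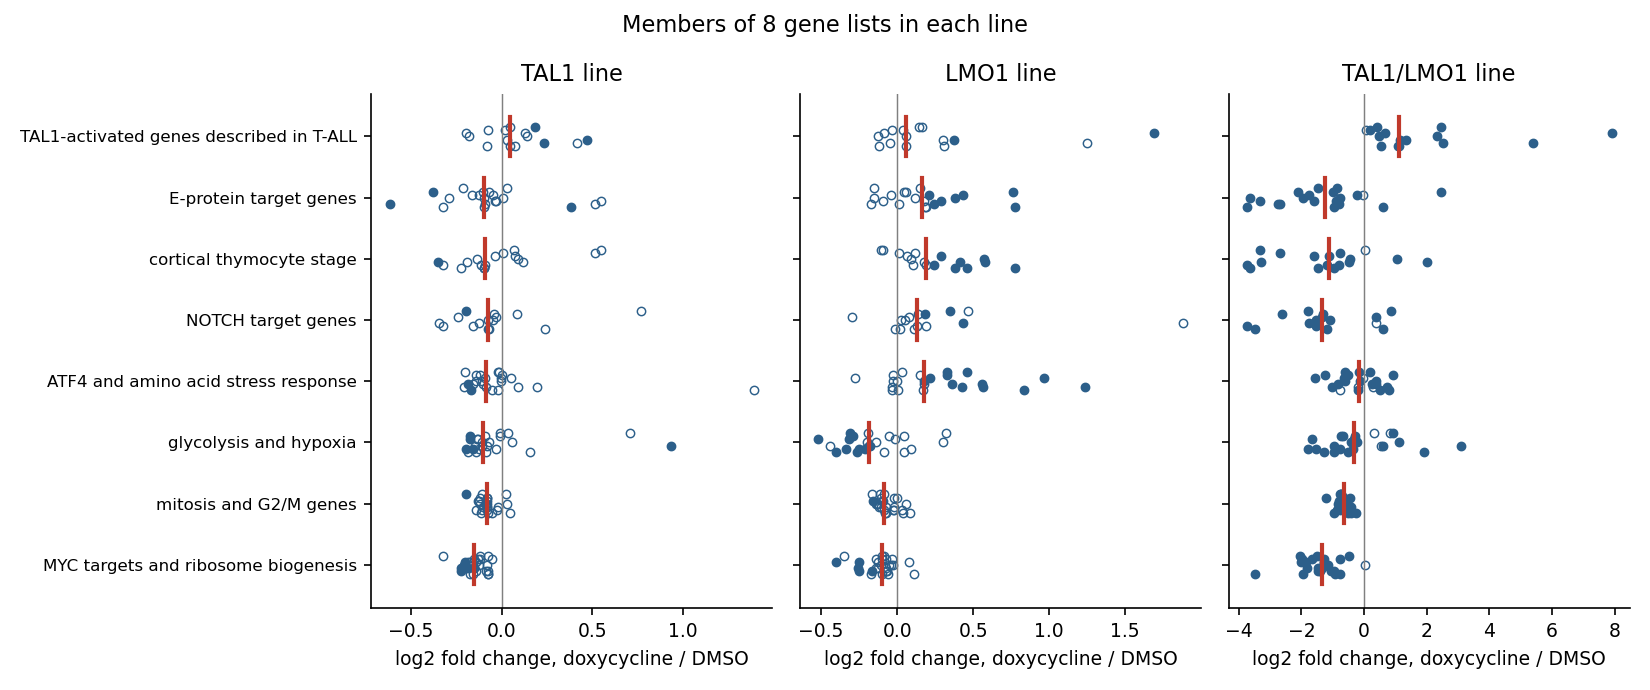
Log2 fold change, doxycycline over DMSO, of every tested member of 8 gene lists in each line; filled points passed the test over all genes, open points did not, and red bars are list medians. The 3 panels have different ranges: the median of the cortical thymocyte list was 0.19 in the LMO1 line and -1.10 in the TAL1/LMO1 line.

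The response of the TAL1/LMO1 line differed from that of the TAL1 line in 7137 genes (2998 more positive, 4139 more negative). It differed from that of the LMO1 line in 7400 (3104 and 4296), and from the sum of both single responses in 5655 (2172 and 3483). By total counts the split was 3546 and 3550 against the TAL1 line and 3773 and 3529 against the LMO1 line, so the balance of both sides depends on the scaling. Against that sum, ALDH1A2 was higher by 6.41 (SE 0.69, adjusted p = 7.7e-06) and SEMA4A by 7.11 (SE 1.39, adjusted p = 2.1e-05), while DOCK1 was lower, at -6.83 (SE 0.09, adjusted p = 3.6e-65). ALDH1A2 was at 5.72 without DMSO replicate 1 of the TAL1/LMO1 line and at 7.74 without DMSO replicate 2, and SEMA4A lay between 6.55 and 7.68 with 1 library left out. FAM196A averaged 2.67 CPM with DMSO in the TAL1/LMO1 line and had 0 counts there with doxycycline, against 2.08 and 2.64 CPM in the TAL1 line and 6.14 and 6.74 CPM in the LMO1 line. ANXA1 went from 1.64 CPM to 0 counts in the TAL1/LMO1 line, from 0.683 to 1.61 CPM in the TAL1 line and from 20.2 to 12.2 CPM in the LMO1 line. TAL1-activated genes were more positive than the sum in 12 of 15 cases, 13 when adjusted over the list alone (camera adjusted p = 8.5e-14; adjusted p = 0.0018 with an estimated correlation). MYC targets were more negative in 25 of 27, the same as adjusted over the list alone (camera adjusted p = 1.9e-24; adjusted p = 0.0018 with an estimated correlation). TAL1 and LMO1 were each higher in the TAL1/LMO1 line than in the single lines. These differences therefore hold a difference in transgene level as well as in the number of transgenes. Each combination of transgenes was also only 1 line, and the lines already differed with DMSO. Line background therefore cannot be told apart from the transgenes.

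The responses of both single lines differed in 153 genes, 63 more positive and 90 more negative in the TAL1 line. IGLL1 had a difference of -1.14 (SE 0.07, adjusted p = 1.3e-19), MFAP4 of -1.19 (SE 0.14, adjusted p = 1.2e-09) and SERINC5 of -1.68 (SE 0.22, adjusted p = 6.5e-08), while ANXA1 had 1.95 (SE 0.39, adjusted p = 0.00067). CFTR (1.79, SE 0.17) and PTPRF (2.72, SE 0.69) also differed, with the limit on genes high in the LMO1 line given above. With 1 library left out PTPRF lay between 2.17 and 3.14. It was at 2.17 (SE 0.77, adjusted p = 0.17) without doxycycline replicate 1 of the TAL1 line, and its adjusted p was 0.059 without DMSO replicate 2. In the TAL1 line PTPRF had 0.197 and 0.129 CPM with DMSO and 1.51 and 0.761 CPM with doxycycline, and in the LMO1 line with DMSO 114 CPM. The ATF4 list was more negative in 12 of 23 cases, 14 when adjusted over the list alone (camera adjusted p = 5.1e-25; adjusted p = 0.0038 with an estimated correlation). E-protein targets were more negative in 7 of 20, 9 when adjusted over the list alone with 1 more positive (camera adjusted p = 1.5e-17; adjusted p = 0.0070 with an estimated correlation). Cortical thymocyte genes were more negative in 7 of 17, 10 when adjusted over the list alone with 1 more positive (camera adjusted p = 8.6e-16; adjusted p = 0.0025 with an estimated correlation).

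The genes that the TAL1 line and the TAL1/LMO1 line both called went mostly the same way. In both, 128 were higher and 131 lower, against 45.6 and 44.1 if the calls were independent, and 19 went opposite ways. Of the 19, 16 rose in the TAL1 line and fell in the TAL1/LMO1 line, against 50.8, and 3 did the reverse, against 39.6. The LMO1 line and the TAL1/LMO1 line shared 89 higher genes and 118 lower ones, against 54.7 and 49.8. A further 79 genes rose in the LMO1 line and fell in the TAL1/LMO1 line, against 60.9, and 25 did the reverse, against 44.8. By DESeq2 the shared higher genes numbered 57 for the first of these pairs of lines and 53 for the second. Both single lines shared 13 higher and 19 lower genes, against 1.89 and 1.34, and by DESeq2 the shared higher genes were 7. Another 16 went opposite ways: 8 rose in the TAL1 line and fell in the LMO1 line, against 1.54, and 8 did the reverse, against 1.64. Since opposite calls of the single lines also exceeded independence, the excess of their shared calls does not by itself show a common response. Across genes, which are not independent replicates, the Spearman correlation of the fold changes was 0.31 between the TAL1 line and the TAL1/LMO1 line, 0.18 between the LMO1 line and the TAL1/LMO1 line and 0.15 between the single lines. Pearson's was 0.18, 0.097 and 0.0077. Among the 13778 genes with a mean of at least 1 CPM, Spearman's was 0.38, 0.21 and 0.21 and Pearson's 0.22, 0.14 and 0.034. In all 3 lines 10 genes rose and 18 fell, against 0.54 and 0.43 if independent. The limit given above for the single lines applies to this comparison too. ITGA4, an integrin, and the signalling factors STAT3 and STAT5B were among those that rose, and ENO1, GAPDH, HK2 and ODC1 among those that fell. Most of these calls depended on single libraries. With 1 library left out in turn, 2 of the 28 genes kept the call in each fit of the TAL1 line, 9 in each fit of the LMO1 line and 28 in each fit of the TAL1/LMO1 line. Only ITGA4 kept it in every fit of all 3 lines. In the TAL1 line ENO1, GAPDH and ODC1 lost the call in each of the 4 fits (highest adjusted p = 0.17, 0.28 and 0.33) and HK2 in 3 (0.49), while STAT3 lost it in 2 (0.091) and STAT5B in 3 (0.34). HK2 also lost it in 1 fit of the LMO1 line (0.056). ITGA4, STAT3 and STAT5B were chosen for mention after their values were seen.

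With DMSO alone the lines already differed, in 5925 genes between the TAL1 line and the LMO1 line, in 7401 between the TAL1/LMO1 line and the TAL1 line, and in 6678 between the TAL1/LMO1 line and the LMO1 line. CD44, an adhesion molecule, averaged 98.2 CPM in the TAL1 line and 26.5 CPM in the TAL1/LMO1 line and had 0 counts in the LMO1 line, at least 1002-fold and at least 270-fold below them. VCAN, a matrix proteoglycan, was at 201 CPM in the TAL1 line and 0.129 CPM, or 4 counts over 2 libraries, in the TAL1/LMO1 line (log2 -10.52, SE 0.72). NELL2 was at 38.1 CPM in the LMO1 line and had 0 counts in the TAL1/LMO1 line, at least 395-fold lower; BEND6 was at least 213-fold lower there than in the TAL1 line. Each fold change with doxycycline was therefore taken within a line.

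The authors' deposited tables gave 98, 113 and 6989 genes with an adjusted p under 0.05 for the TAL1 line, the LMO1 line and the TAL1/LMO1 line. Of these, 95, 112 and 6963 were also called here, all with the same sign. The calls here numbered 299, 349 and 9812, so most calls here in the single lines were not calls of the authors. The authors gave an adjusted p for 28169, 3705 and 17528 genes, so their counts rest on unlike sets of genes. The correlation across genes between the authors' log2 fold changes and those computed here was 0.990, 0.988 and 0.999.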

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

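The results of the next paragraph are differences between lines in the response to doxycycline, and each difference was tested itself. The genes that changed alike in all 3 lines and the rises in the TAL1 line, described last, are not such differences. The tests of explanations were chosen after the result was seen, except the comparison with genes of similar abundance, which was written before its result was seen.

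The number of genes whose response differed was 7137 between the TAL1/LMO1 line and the TAL1 line, 7400 between the TAL1/LMO1 line and the LMO1 line, 153 between the single lines, and 5655 between the TAL1/LMO1 line and the sum of the single responses. For example, the response of the TAL1/LMO1 line exceeded that of the TAL1 line by 2.27 for RUNX1 (SE 0.07, adjusted p = 1.7e-42) and differed by -3.41 for MYC (SE 0.07, adjusted p = 3.0e-53). In 3 lists the single lines were called in opposite directions. The adjusted p of the difference was 1.5e-17 for E-protein targets (0.0070 with an estimated correlation), 6.2e-10 for NOTCH targets (0.025) and 5.1e-25 for the ATF4 list (0.0038). The call in the TAL1 line itself was lost in all 3 lists with an estimated correlation. The TAL1/LMO1 line and the LMO1 line were also called in opposite directions in 3 lists. There the adjusted p of the difference was 2.4e-12 for E-protein targets (0.0094 with an estimated correlation), 1.2e-10 for cortical thymocyte genes (0.0039) and 7.6e-09 for NOTCH targets (0.025). With an estimated correlation the NOTCH list itself was not called in the TAL1/LMO1 line (0.053). The E-protein, cortical thymocyte and NOTCH lists share members, as given above, so they are not separate results. The single lines also called 16 genes in opposite directions, and 3 of them, IGLL1, CFTR and the receptor constant region TRGC2, kept both calls with any 1 library left out. NOTCH3 kept its call in the TAL1 line in 1 of 4 such fits (highest adjusted p = 0.17), and CFTR lost its call there after the subtraction of trace RNA described below (0.060). TRGC2 was chosen for mention after its values were seen.

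The first pattern is the size of the TAL1/LMO1 response. With the transgene left out, 93.1% of the 277 genes called in both the TAL1 line and the TAL1/LMO1 line went the same way (95% interval 89.5 to 95.8). A higher TAL1 level alone could therefore account for the direction of these genes, and it cannot be told apart from a joint effect of TAL1 and LMO1, since TAL1 was 22.9 times as high and LMO1 was added in the same line. Of the 310 genes called in both the LMO1 line and the TAL1/LMO1 line, 66.5% went the same way (60.9 to 71.7) and 104 went the opposite way, such as the NOTCH3 and CD1E genes. For these genes, a small part of the 9812 called, that argues against a higher LMO1 level alone. It does so only if each gene moves one way as LMO1 rises and both lines respond alike to LMO1. The second condition was not tested, and the lines already differed in 6678 genes with DMSO. Line background therefore cannot be told apart from the causes named here.

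The second pattern is the 28 genes that changed alike in all 3 lines, such as ENO1 (-0.17, -0.32 and -1.65 in the TAL1, LMO1 and TAL1/LMO1 lines) and STAT3 (0.24, 0.24 and 2.29). Only 1 of them, ITGA4, kept its calls in all 3 lines with any 1 library left out, so the set is uncertain in the single lines. For a bias of abundant mRNAs, the medians of 1915 genes of similar abundance were at most 0.222 times those of the 18 that fell, in any of the 3 lines. They were -0.02, -0.02 and -0.21 in the TAL1, LMO1 and TAL1/LMO1 lines, so a shift shared by such genes was small in the single lines. The 18 were picked because they passed as lower, which enlarges their medians. The ratio therefore cannot decide how far such a bias helped their calls. The ATF4 list did not rise in every line. It differed between the single lines (camera adjusted p = 0.0038 with an estimated correlation), and its median was -0.09 in the TAL1 line. That argues against a visible stress response through ATF4 to doxycycline in every line. The single lines also differed with DMSO and in their transgene, and either could hide such a response, so it is not excluded. Doxycycline by another route cannot be told apart from an effect that the transgenes share, because 0 groups came from a line without a transgene. Both remain open.

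The third pattern is the rise in the TAL1 line of genes that the LMO1 line expresses far more highly, PTPRF, PTMS and CFTR; PTMS was chosen after its values were seen. Of 16 such marker genes, 13 outside this pattern exceeded their DMSO level by a median of 1.56% of the LMO1-line level in doxycycline replicate 1 of the TAL1 line, and by -0.067% in replicate 2. Here trace RNA means either RNA of that line in the sample or its reads assigned to the wrong library, since counts per gene do not separate them. Taking that share out moved PTPRF from 2.73 (SE 0.69) to 1.22 (SE 0.81) and PTMS from 1.43 (SE 0.42) to -0.09 (SE 0.53), so both calls ended because the fold shrank and the error grew. PTMS was at 0.66 (SE 0.54) without replicate 1, within 2 SE of 0, and trace RNA of the LMO1 line is a candidate explanation for its rise. PTPRF, at 0.197 and 0.129 CPM with DMSO, was at 1.51 CPM in replicate 1 but also at 0.761 CPM in replicate 2, where the markers had no excess. Without replicate 1 its change was 2.17 (SE 0.77, adjusted p = 0.13). So few counts leave open whether trace RNA is the whole cause of its rise. Markers of the TAL1/LMO1 line exceeded DMSO by at most 0.0172%, which argues against that line as the source for PTPRF and PTMS. CFTR moved from 1.32 (SE 0.16) to 0.67 (SE 0.18, adjusted p = 0.060), more than 2 SE from 0, and was 0.98 (adjusted p = 1.0e-06) without replicate 1, so whether trace RNA is the whole cause of its rise stays open, beside an effect of TAL1.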

How the results depend on the processing

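The subtraction of trace RNA, in each of its 3 forms, and the lists without TAL1 and LMO1 were chosen after seeing the data; the other alternatives were planned. The number of called genes of each of the 10 comparisons, both directions together, changed by no more than 1.5 times under DESeq2's size factors, total counts, no filter or the stricter filter. Overlaps and list tests were not run under the last 3, and of these list medians were computed only under total counts. Over all comparisons, 10 named genes lost a call under DESeq2 and 7 gained one, where only genes that DESeq2 gave an adjusted p were counted. These numbers were 12 and 5 under total counts, 9 and 1 with no filter, and 3 and 2 under DESeq2's size factors. Under those size factors 1 called list lost its call, and under the replicate block 1 did.

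An absolute log2 fold change of at least 1 left 29, 20 and 2414 genes in the TAL1, LMO1 and TAL1/LMO1 lines. It left 1678, 1802, 27 and 1392 for the differences of TAL1/LMO1 to TAL1, to LMO1, of TAL1 to LMO1 and of TAL1/LMO1 to the sum. For the DMSO comparisons of TAL1 to LMO1, TAL1/LMO1 to TAL1 and TAL1/LMO1 to LMO1 it left 1239, 1601 and 1389. Fewer genes follow from the stricter limit itself.

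Fitting the 4 libraries of the TAL1 line alone gave 523 genes, and the cause was not tested. DESeq2 called 218 genes in the LMO1 line, where its own filter left 8526 genes without an adjusted p, among them 66 of the genes called by edgeR. In the TAL1 line DESeq2 left 10104 genes without one, among them 81 of the genes called by edgeR. Its overlaps of higher genes were 7 (TAL1 and LMO1 lines), 57 (TAL1 and TAL1/LMO1 lines) and 53 (LMO1 and TAL1/LMO1 lines). Genes called by both tools were 169, 205 and 8193, all with the same sign. With an estimated correlation 3, 8 and 6 lists were called in the TAL1, LMO1 and TAL1/LMO1 lines, and fry called 7, 14 and 21; the preset correlation called 14, 13 and 14. Without TAL1 and LMO1 in the lists it called 12, 13 and 13.

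A replicate block, in which libraries with the same replicate number share an effect, gave 21 higher genes shared by the TAL1 and LMO1 lines instead of 13. The cause was not tested. Over 15 pairs of groups the correlation of the deviations between replicates lay between -0.015 and 0.055. These correlations are over all tested genes, also those with few counts, so they cannot exclude an effect shared by replicate number.

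Leaving out 1 library gave 100 to 155 genes in the TAL1 line and 155 to 284 in the LMO1 line; these fits have fewer libraries. In the TAL1/LMO1 line it was 8726 to 9023. For the induction of TAL1 and LMO1, TAL1 in the TAL1 line was 3.16 to 3.43, and no longer called without DMSO replicate 2. In the DMSO libraries, TAL1 in the TAL1/LMO1 line against the TAL1 line (0.39) lay between -0.37 without TAL1/LMO1 replicate 2 and 0.88 without replicate 1. LMO1 in the TAL1/LMO1 line against the LMO1 line (0.37) lay between -2.64 (adjusted p = 0.0059, a call) without TAL1/LMO1 replicate 2 and 1.27 without replicate 1, and was -0.10 without LMO1 replicate 2. Of the fits of named genes that left out 1 library, 1176 kept the call or its absence, 166 lost a call, 11 gained one and 3 changed sign.

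After subtraction of trace RNA, RAG2, not called before it, changed sign in the TAL1 line (-0.23, and -1.72 and -0.19 in the other forms). PTPRF changed sign in the difference between the single lines in 1 form (-0.00901). Both follow from subtracting RNA of a line where these genes are high. The form that summed the markers removed all counts of PTPRF and PTMS in the TAL1 line and all DMSO counts of CFTR (8.25), so it decides nothing for these genes. In the other 2 forms all 3 lost their calls; CFTR was 0.67 (adjusted p = 0.060), and 0.70 (adjusted p = 0.13) with a negative excess kept.

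The share of called genes that were higher in the TAL1 line was 53.5%. It was 79.1% by total counts, 48.0% with DESeq2's size factors in edgeR and 35.3% by DESeq2 itself. DESeq2 gave no adjusted p to 81 genes that edgeR called in that line, so its share does not reflect scaling alone. In the TAL1/LMO1 line the share was 47.3%, but 56.7% by total counts. Between the DMSO libraries of the TAL1/LMO1 line and the LMO1 line it was 49.8%, and 62.5% by total counts. Under each scaling the median fold change of all genes lay within 0.0854 of 0. Depth limits genes near 0.198 CPM, the level of 3 counts in a library, as for LMO1 in the TAL1 line.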

Other observations

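The values in this part test no explanation. In the TAL1/LMO1 line, lists of other lineages and of cell death were not called by camera, although single members were, and fry called the erythroid, stem, epithelial and BCL2 family lists (adjusted p = 0.00011, 0.00057, 0.031 and 1.1e-05). Among erythroid genes (camera adjusted p = 0.096), HEMGN rose from 6.59 to 19.9 CPM and EPOR, the erythropoietin receptor, by 1.48 on the log2 scale. Stem and progenitor genes (0.51) went both ways, with HHEX at 2.32 and FLT3, a receptor kinase, at -2.51. Members of the BCL2 family (0.16) included BMF at 0.91, BCL2 at 0.77 and BID at -0.64. B-cell genes (0.75) included CD79B, which went from 4.53 to 9.48 CPM, and natural killer genes (0.77) included NKG7 at 0.79 and GNLY at -3.06. Epithelial genes had an adjusted p of 0.75. The myeloid list had 1 tested member and was not tested as a list.

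In the TAL1 line, the lists not called by camera were those of erythroid, stem, B-cell, epithelial, cortical thymocyte (adjusted p = 0.18), immediate early (0.17), interferon (0.52), cholesterol and BCL2 family genes. In the LMO1 line these were GIMAP, erythroid, stem, B-cell, natural killer, epithelial, immediate early, interferon, p53 and BCL2 family genes, of which fry called the BCL2 family (adjusted p = 0.013).

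Between the DMSO libraries of the TAL1/LMO1 line, ALDH1A2 was at 0.834 CPM in replicate 1 and 3.41 CPM in replicate 2, and SEMA4A at 0.962 and 1.93 CPM, alongside TAL1 at 3.08 and 7.34 CPM.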
